A study of Rattus norvegicus with 9 samples.

How the data were processed

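Gene expression was measured in lumbar dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, of Sprague-Dawley rats. Diabetes was induced with streptozotocin (STZ), a toxin of the insulin-producing beta cells of the pancreas. The labels name 3 groups, which are normal rats given vehicle, STZ-injected rats given vehicle and STZ-injected rats given FK1706, an immunophilin ligand. Its dose is not given in the sources used here. Ganglia were taken the day after 1, 2 or 3 weeks of dosing. Each of the 9 arrays holds the pooled RNA of 5 rats, so each group has 1 array per week. The p-values therefore measure the spread between pools, not between rats. No group has more than 1 pool in a week, so that spread includes any change of a group difference from week to week.

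The deposited values are an intensity per probe set on a linear scale, made with MAS5 according to the submitters' processing notes, which give no version. The design had assumed that they were already scaled to a common level. They were not, since the 2% trimmed mean signal fell from 534 in the week 1 normal array to 361 in the week 3 FK1706 array. Quantile normalization of the log2 values, which had been set as an alternative, was therefore taken as the normalization. That choice was made after the signal levels had been seen and before any gene was tested. The deposited scale was kept as an alternative, added after the data had been seen. On the deposited scale the median log2 difference of all genes was -0.10 for STZ vehicle against normal, -0.07 for STZ FK1706 against STZ vehicle and -0.17 for STZ FK1706 against normal. All differences given are relative to that shift unless the deposited scale is named.

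The array's 15923 probe sets include 57 controls. Of the other 15866, 12783 had 1 gene symbol in the platform's annotation, 312 had several and 2771 had none. Symbols were checked through Entrez gene identifiers against the GRCr8 gene table, which held 12754 of them and changed 0 symbols. The probe set with the highest mean stood for each of 10411 genes. An offset of 18.7 signal units, the 10th percentile of all values, was added before the log2 step. Genes with a mean at or above the 40th percentile of probe sets were tested, which left 6989.

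Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with group and week as factors over all 9 arrays and 4 residual degrees of freedom. Week entered as a block, because the design samples every group once in each week. After each gene's group means had been removed, arrays of the same week correlated across genes with r from 0.01 to 0.33. All p-values were two-sided and adjusted by Benjamini-Hochberg, and a gene passed at an adjusted p under 0.05. Weeks were compared with a moderated F test. A second model with a linear week term per group, with 2 residual degrees of freedom, tested whether differences grew or shrank over the weeks. Genes at least 1.5-fold apart in 1 direction in each of the 3 weeks were counted without a model, beside the counts from the 3 other ways of swapping the labels of the groups within weeks.

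Marker and pathway lists, 31 in number, covered the cell types a ganglion pool could hold and programs of neurons, metabolism, stress and inflammation. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01, which compares the genes of a list with all other genes. Camera with an estimated correlation stands beside it, and so does fry, which tests the genes of a list against no change instead of against other genes. No change means no difference after quantile normalization. In all, 29 lists were tested. The lists of lymphocyte genes and red blood cell genes had too few genes and were not tested.

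Genes named in the text follow a rule. For each comparison of groups it takes up to 10 genes per direction by log2 difference among those that passed with the same sign in all 3 weeks. Open places go to genes at least 1.5-fold apart in each week, given as values that did not pass. For each list described, it takes up to 4 members with the largest moderated t, and for weeks the 5 highest and 5 lowest. Ins1, Ins2 and the FK506-binding proteins are given whatever their values. Which lists to describe by their members was chosen after the list tests had been run. Clock, muscle and myelin genes outside this rule were chosen after their values had been seen.

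The models were tested on simulated data. Noise was drawn independently for each array from each gene's variance as moderated by limma, not from its observed variance, so recovery in real data may differ. For STZ vehicle against normal, 37% of 1.3-fold, 74.4% of 1.5-fold and 99.6% of 2-fold changes in 6989 genes were recovered, and 7.24% of calls were false. For STZ FK1706 against STZ vehicle the shares were 39.2%, 79.6% and 98.1%, with 5.72% false, and for STZ FK1706 against normal 32.8%, 74.3% and 98.6%, with 6.17% false. Over 5 runs these simulations gave 774, 787 and 746 calls in that order, far more than the real data. Many true changes ease the adjusted threshold, so recovery may be lower where few genes change. A list of independent simulated genes, all with the same spread, was shifted by -0.2. It was called in 10 of 10 runs, and in 4 of them with an estimated correlation.

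The groups, the models, the gene lists, the rule for named genes and the alternatives other than the deposited scale were set before the data were examined. Alternatives were median scaling, offsets of 1 and at the 30th percentile, no filter, a filter at the 60th percentile, every probe set on its own, week left out of the model, a prior without a trend, only the arrays of the groups compared, and each array or week left out. Minimum folds of 1.3 and 2 were also counted. Figures were drawn with matplotlib 3.10.9. MAS5 detection calls and probe-level intensities were not used here.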

Results

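Expression was measured in pooled lumbar DRG of normal vehicle-treated rats, STZ-injected vehicle-treated rats and STZ-injected rats treated with FK1706, with 3 arrays per group, 1 for each of weeks 1, 2 and 3. The trimmed mean deposited signal was 534, 485 and 386 in the normal arrays of weeks 1, 2 and 3. It was 517, 423 and 366 in the STZ vehicle arrays and 466, 408 and 361 in the FK1706 arrays. Across probe sets, arrays correlated with r between 0.965 and 0.986. The number of arrays limits the precision of every value below, and group values are log2 signals with the SD over 3 pools, 1 from each week. That SD thus includes differences between weeks.

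The comparison of STZ vehicle with normal vehicle asks which DRG transcripts differ in diabetic rats. Txnip, whose product inhibits thioredoxin and restrains glucose uptake, was 1.59-fold higher in STZ rats, at 11.52 ± 0.105 (SD, n = 3) against 10.85 ± 0.127 in normal rats. Col1a1, a chain of type I collagen, was 1.76-fold lower (11.27 ± 0.309 against 12.08 ± 0.344, n = 3), and Col2a1, the collagen of cartilage, was 2.27-fold lower (7.64 ± 0.407 against 8.82 ± 0.347, n = 3). Igf1, which encodes insulin-like growth factor 1, a trophic factor for sensory neurons, was 1.73-fold lower (8.45 ± 0.248 against 9.24 ± 0.138, n = 3).

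With limma, 7 of 6989 genes passed, 1 higher and 6 lower, and each had the same sign in all 3 weeks. The log2 difference of Txnip was 0.67 (SE 0.072, adjusted p = 0.0103), with 0.70, 0.60 and 0.70 in weeks 1, 2 and 3. Col2a1 fell by 1.18 (SE 0.145, adjusted p = 0.0106), Col1a1 fell by 0.82 (SE 0.094, adjusted p = 0.0103) and Igf1 fell by 0.79 (SE 0.101, adjusted p = 0.0106). The others were Timp1, an inhibitor of matrix metalloproteinases (-0.55, SE 0.083, adjusted p = 0.0429), the type III collagen gene Col3a1 (-0.54, SE 0.068, adjusted p = 0.0106) and the type I collagen gene Col1a2 (-0.53, SE 0.082, adjusted p = 0.0492). Second probe sets gave -0.92 for Col1a1, -0.43 for Col1a2 and -0.56 for Igf1, but only -0.08 (SE 0.161) for Col2a1. At least 1.5-fold apart in each week were 5 genes, Txnip higher and Col2a1, Col1a1, Igf1 and Acp5 lower, against 0, 1 and 0 genes under the swapped labels. Acp5, an acid phosphatase of osteoclasts, had -0.71 and did not pass (adjusted p = 0.218).

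At an unadjusted p under 0.05, 606 genes differed where 349.5 would by chance. The deposited scale gave 16 genes (1 higher, 15 lower), among them all 7. The limma count was 0 without the week 1 STZ vehicle array, the week 3 normal array or the week 3 STZ vehicle array (481, 490 and 428 genes at an unadjusted p under 0.05), and 3 without the week 2 STZ vehicle array. It was 0 without week 1 (687 unadjusted), 4 without week 2 and 1 without week 3. It was 1 with week left out as a block, 0 with no filter (790 unadjusted) and 0 with a prior without a trend (569 unadjusted).

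**Figure D1:**
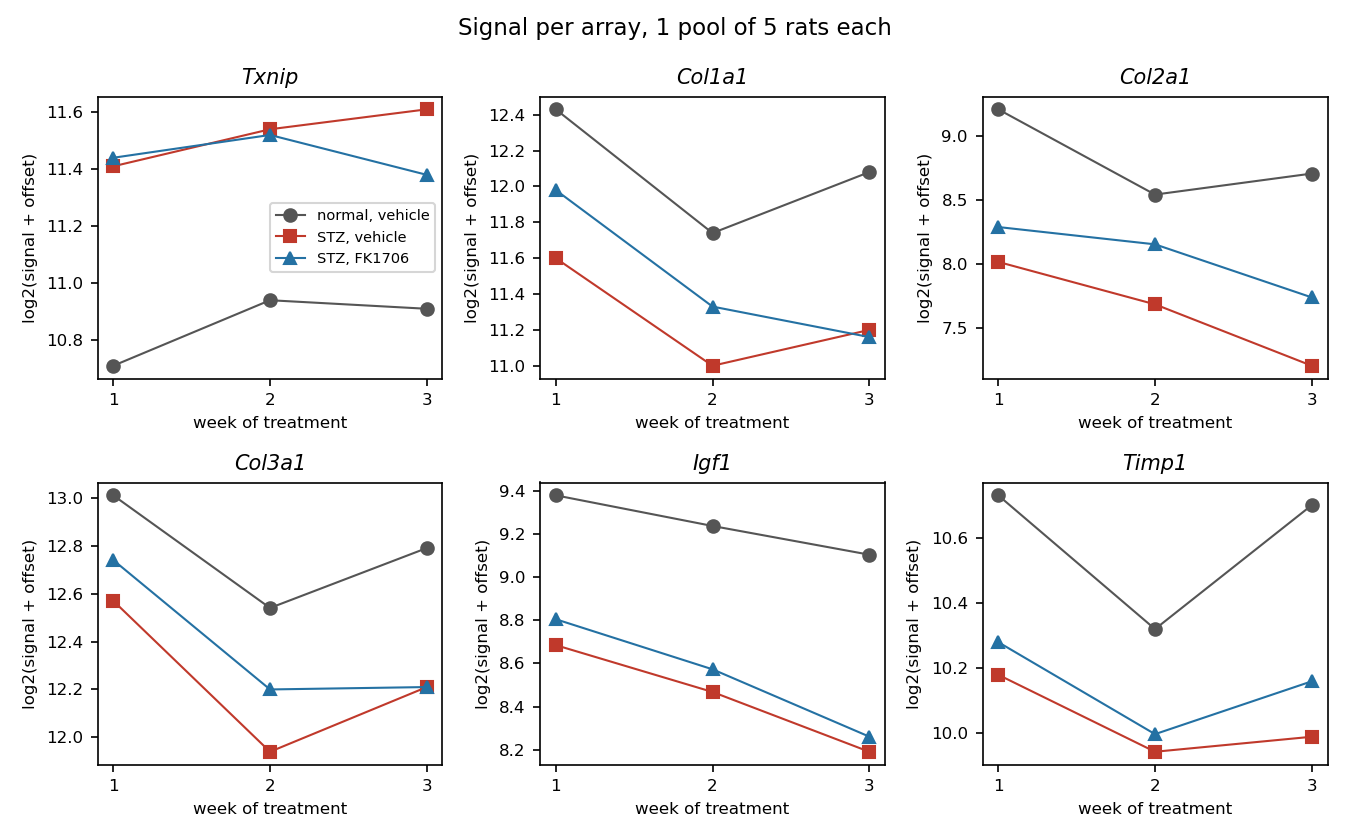
Log2 signal (with the offset added) of 6 genes that passed in STZ vehicle against normal vehicle, plotted against week of treatment, with 1 point per array and 1 line per group. Txnip lies higher in both STZ groups than in normal rats in each week, and Col1a1, Col2a1, Col3a1, Igf1 and Timp1 lie lower.

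By list, 7 of 29 passed in STZ vehicle against normal vehicle, 1 higher and 6 lower than the other genes tested, 0 of them with an estimated correlation. Other splits of the same arrays called 1 to 5 lists at the preset correlation. Fry asks another question, whether the genes of a list differ from no change after normalization. Normalization took out a median of -0.10 here, so higher than no change need not mean higher on the deposited scale. With fry 4 lists passed, 3 of them among the 7 (matrix, cartilage and bone, and glycolysis), and ion channels were higher than no change (fry adjusted p = 0.00984). Fibroblast and extracellular matrix genes were lower (adjusted p = 3.18e-16, and adjusted p = 0.116 with an estimated correlation). Of 39 members, 4 fell over all genes tested (Col1a1, Col3a1, Timp1 and Col1a2) and 12 adjusted over the list alone. Lower in every week were 23, where chance gives 12.5%, and the median log2 differences in weeks 1, 2 and 3 were -0.22, -0.24 and -0.23. Cartilage and bone genes were lower (adjusted p = 4.89e-09, and adjusted p = 0.0865 with an estimated correlation), with a median of -0.62 over 6 members. Of these, 1 fell over all genes tested (Col2a1) and 5 adjusted over the list alone. They include Col10a1, a collagen of growth plate cartilage (-0.94, adjusted p = 0.158), and Cnmd, which encodes chondromodulin (-0.53, adjusted p = 0.235).

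Myelinating Schwann cell genes were lower as a list (adjusted p = 3.62e-05, and adjusted p = 0.252 with an estimated correlation), with a median of -0.20 over 17 members. Over all genes tested 0 fell, with 7 lower at an unadjusted p under 0.05 in limma, and 4 fell adjusted over the list alone. These were Prx (-0.31), which encodes periaxin, the myelin enzyme gene Cnp (-0.36), the myelin protein gene Mal (-0.24) and Sox10 (-0.39), the transcription factor of the Schwann cell lineage. Among other members, Mbp (-0.06, SE 0.051) and Pmp22 (-0.03, SE 0.044) hardly differed. Mag (-0.07, SE 0.208) and Drp2 (0.04, SE 0.134) were too imprecise to tell. Pllp had -0.29, Cldn19 -0.23 and Cd9 -0.20, while Mpzl2 had 0.23. Fatty acid synthesis genes were lower (adjusted p = 0.00104, and adjusted p = 0.252 with an estimated correlation). Over all genes tested 0 of 16 members fell, with 5 lower at an unadjusted p under 0.05 in limma, and 1 fell adjusted over the list alone, malic enzyme Me1 (-0.35). Dgat2, for triglyceride synthesis, had -0.44, the desaturase gene Fads1 -0.22 and Srebf1, the regulator of the pathway, -0.50.

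Glycolysis, glucose transport and polyol genes were higher as a list (adjusted p = 0.0354, and adjusted p = 0.252 with an estimated correlation), with a median of 0.06 over 22 members. Txnip rose over all genes tested. It had a moderated t of 9.20, where the next in size was -3.74 for Akr1b1. The list was not tested without Txnip, so its call does not show a general rise of glycolysis genes. Adjusted over the list alone, Txnip rose and Akr1b1, the aldose reductase of the polyol pathway, fell (-0.25), while Pgam1 had 0.13 and Gpi 0.16. This list did not pass on the deposited scale (adjusted p = 0.126), with no filter (0.185) or with a filter at the 60th percentile (0.0556). It also did not pass without the normal arrays of weeks 1 (0.117) or 3 (0.0772), the STZ vehicle arrays of weeks 1 (0.0959) or 2 (0.0511), week 1 (0.105) or week 3 (0.0701).

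Interferon-stimulated genes were lower (adjusted p = 0.015, and adjusted p = 0.252 with an estimated correlation), with 0 of 19 members passing in limma over all genes or adjusted over the list alone and 1 lower at an unadjusted p under 0.05. Ifitm1 had -0.26, Ifitm3 -0.14, the immunoproteasome gene Psmb10 -0.22 and the antigen-loading gene Tapbp -0.19. Mast cell and neutrophil genes were lower (adjusted p = 0.0354, and adjusted p = 0.648 with an estimated correlation), with 0 of 5 members passing over all genes, 3 lower at an unadjusted p under 0.05 and 2 adjusted over the list alone. These were S100a9, a neutrophil calcium-binding protein gene (-0.64), and the defensin gene Np4 (-0.97), beside -0.73 for the mast cell tryptase gene Tpsb2 and -0.10 for S100a8. The medians of the mast cell and neutrophil list were -0.09, -0.25 and -1.12 in weeks 1, 2 and 3. Interferon genes did not pass without week 1 (0.33), its normal array (0.175), its STZ vehicle array (0.232) or the week 2 STZ vehicle array (0.0511). Mast cell and neutrophil genes did not pass on the deposited scale (0.075), with no filter (0.185), or without the normal arrays of weeks 1 (0.117) or 3 (0.159), the week 3 STZ vehicle array (0.638), week 1 (0.0608) or week 3 (0.23).

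Nerve injury and regeneration genes did not pass as a list (adjusted p = 0.784). Over all genes 0 of 15 passed in limma, with 2 at an unadjusted p under 0.05, and 1 fell adjusted over the list alone, Npy, a neuropeptide induced in large neurons after axotomy (-0.49, adjusted p = 0.273 over all genes). The injury neuropeptide gene Gal had -0.56, Smad1 0.29 and Anxa1 -0.16. The median of that list was 0.02 and its mean -0.01, of opposite sign. Nociceptor genes did not pass (adjusted p = 0.998), with 0 of 21 members passing either over all genes or adjusted over the list alone, and 2 at an unadjusted p under 0.05 in limma. The peptide gene Cartpt had -0.35, the sodium channel genes Scn11a and Scn10a 0.16 and -0.20, and the ATP receptor gene P2rx3 0.15. Neurotrophic factor, insulin and IGF family genes did not pass as a list (adjusted p = 0.897), and Igf1 was the 1 of 24 members that fell, both over all genes and adjusted over the list alone. Igfbp5, an IGF-binding protein gene, had -0.38, Igf2r 0.17 and the GDNF receptor gene Gfra1 -0.16.

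Skeletal muscle transcripts differed between pools. Their median difference between STZ vehicle and normal was 0.32 in week 1, -1.75 in week 2 and 0.17 in week 3, and the list did not pass (adjusted p = 0.0688, and adjusted p = 0.749 with an estimated correlation). Over the weeks Acta1 had -0.64, Myl1 -0.57, Tnnt3 -0.51 and Myh1 -0.11. In weeks 1, 2 and 3 Acta1, skeletal muscle actin, was at 9.16, 10.77 and 9.86 in normal, 9.46, 8.48 and 9.92 in STZ vehicle and 9.24, 10.13 and 8.41 in FK1706 rats. Myl1, a myosin light chain gene, was at 7.90, 9.50 and 8.24 in normal, 8.30, 7.24 and 8.40 in STZ vehicle and 7.39, 8.44 and 6.56 in FK1706 rats. The week 2 difference thus holds both the highest Acta1 value, in the normal pool, and a low one, in the STZ vehicle pool. The muscle list was called lower without the normal arrays of weeks 1 (0.0207) or 3 (0.0428), the STZ vehicle arrays of weeks 1 (0.00851) or 3 (7.6e-05), the week 3 FK1706 array (0.0489), week 1 (0.00873) or week 3 (0.000539). Without week 2 it was called higher (0.0491).

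The comparison of STZ FK1706 with STZ vehicle asks which transcripts differ with the drug in diabetic rats. In limma 0 genes passed, with 219 at an unadjusted p under 0.05 where 349.5 would by chance and a smallest adjusted p of 0.999. Fibroblast and extracellular matrix genes were higher as a list, by a median of 0.08 (adjusted p = 0.00425, and adjusted p = 0.95 with an estimated correlation). Among them Mfap4, a microfibril-associated protein gene, had 0.41, Mfap5 0.23, Col1a1 0.22 and the fibrillin gene Fbn1 -0.31, and none of these genes passed.

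That list was the 1 of 29 that passed, and it did not pass with fry (adjusted p = 0.664). Of its 39 members 0 passed in limma over all genes or adjusted over the list alone, 3 were higher and 1 lower at an unadjusted p under 0.05, and 9 were higher and 2 lower in each week. Its medians were 0.14, 0.08 and 0 in weeks 1, 2 and 3. The matrix list did not pass without the week 1 STZ vehicle array (0.0676), the FK1706 arrays of weeks 1 (0.219) or 2 (0.565), week 1 (0.196) or week 2 (0.324), nor with week left out as a block (0.058). Both this list and the comparison with normal rats use the same STZ vehicle arrays, with opposite sign, so a low value there gives a higher value here without any effect of the drug.

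Cartilage and bone genes had Col2a1 at 0.42, Acp5 at 0.36, the osteoclast protease gene Ctsk at 0.28 and Col9a2 at -0.11, and the list did not pass (adjusted p = 0.111). It passed on the deposited scale (adjusted p = 0.0134) and without the week 2 STZ vehicle array (0.0496). Nerve injury genes (adjusted p = 0.974) had Npy at 0.23, Vgf at -0.19, Stat3 at -0.11 and Jun at -0.13. Neurotrophic and IGF family genes (adjusted p = 0.879) had the IGF1 receptor gene Igf1r at 0.33, the insulin receptor gene Insr at 0.21, the neurotrophin receptor gene Ntrk3 at -0.29 and the persephin gene Pspn at 0.27. Nociceptor genes (adjusted p = 0.935) had Cartpt at 0.37, the substance P precursor Tac1 at -0.17, Kcnip4 at -0.20 and the sodium channel Scn9a at 0.17. In each of these 4 lists 0 members passed in limma over all genes or adjusted over the list alone, with 2, 0, 1 and 2 members at an unadjusted p under 0.05.

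Skeletal muscle genes, markers of another tissue, went both ways in STZ FK1706 against STZ vehicle, with medians of -0.26, 0.74 and -0.77 in weeks 1, 2 and 3, and the list did not pass (adjusted p = 0.707, and adjusted p = 0.95 with an estimated correlation). It was called lower without the week 2 STZ vehicle array (1.62e-13) or without week 2 (2.78e-10). Over the weeks the slow troponin gene Tnni1 had 0.49, Myh1 -0.12, the fast troponin gene Tnnc2 -0.61 and the calcium pump gene Atp2a1 -0.48. Mast cell and neutrophil genes had medians of 0.02, -0.32 and 1.45 in weeks 1, 2 and 3, and the list did not pass (adjusted p = 0.111, and adjusted p = 0.95 with an estimated correlation). It was called higher on the deposited scale (0.00952), without the STZ vehicle array (0.000301) or the FK1706 array (0.00846) of week 2, and without week 2 (0.000272). S100a9 had 0.51, Np4 0.47, Tpsb2 0.46 and S100a8 0.21. In both lists 0 members passed in limma over all genes or adjusted over the list alone, with 1 member each at an unadjusted p under 0.05.

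FK506-binding proteins, cyclophilins and calcineurin subunits did not pass as a list in STZ FK1706 against STZ vehicle (adjusted p = 0.879), and 0 of 25 members passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 in limma. Fkbp1a, which encodes FKBP12, the main binding protein of FK506, had 0.11 (SE 0.061), and Fkbp4, which encodes FKBP52, -0.21 (SE 0.13). Higher values were those of Fkbp15 (0.30), Fkbp8 (0.11), Fkbp3 (0.09) and Fkbp9 (0.02, and -0.05 on the deposited scale). Lower values were those of Fkbp14 (-0.22), Fkbp5 (-0.22), Fkbp2 (-0.17), Fkbp1b (-0.07) and Fkbp10 (-0.01). The NFAT gene Nfatc4 had 0.26. At least 1.5-fold apart in each week was 1 gene, Bmt2, a regulator of TORC1 signalling (-0.84, SE 0.162, adjusted p = 0.999), against 1, 5 and 0 genes under the swapped labels.

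Across genes, which are not independent replicates, the differences of STZ vehicle from normal and of FK1706 from STZ vehicle correlated with r = -0.40 when pooled over weeks. Unchanged simulated groups, which share the STZ vehicle arrays in the same way, gave a mean of -0.50 and a range of -0.53 to -0.47, so the observed value was less negative than all of them. Their arrays were independent, while STZ vehicle and FK1706 arrays of the same week correlated with r of 0.287, 0.0285 and 0.325 in weeks 1, 2 and 3 once group means had been removed. In pairs of different weeks, which share no array, the covariance was -0.000813, within the simulated range of -0.00136 to 0.000811.

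**Figure D2:**
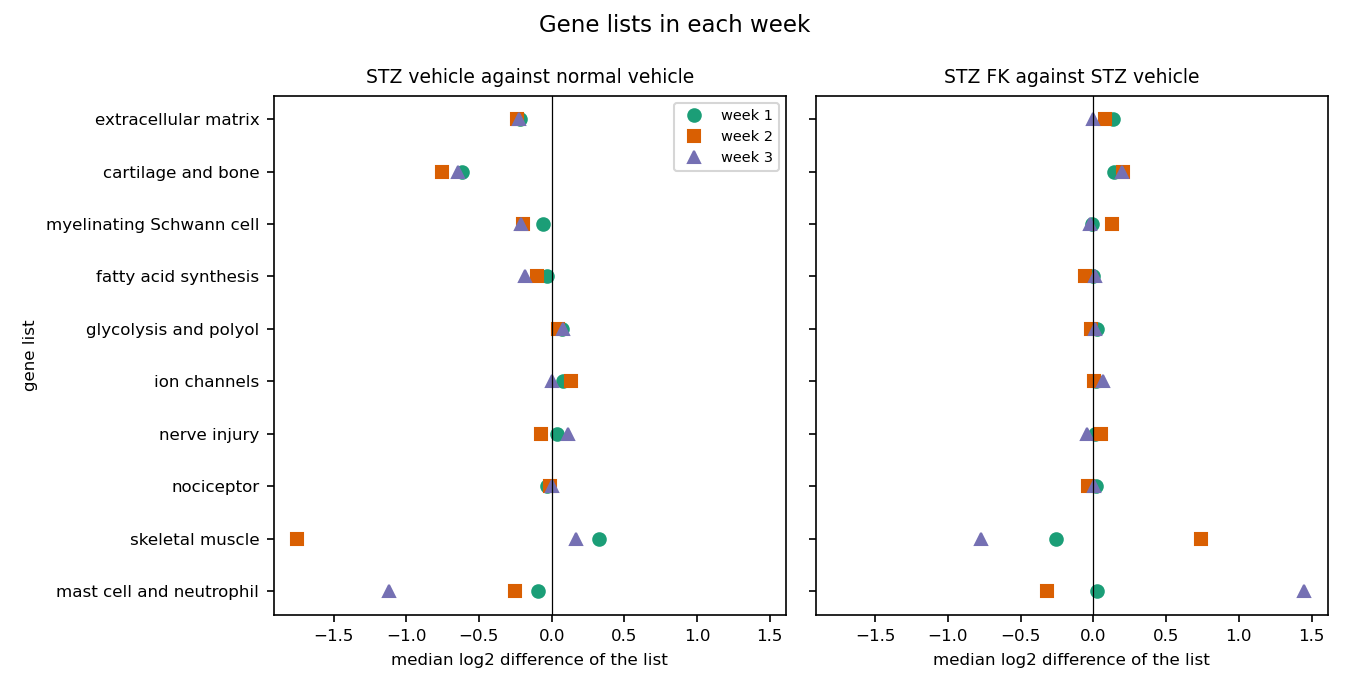
Median log2 difference of 10 gene lists in each week, for STZ vehicle against normal vehicle and STZ FK1706 against STZ vehicle, with 1 point per week. The extracellular matrix list lies at -0.22, -0.24 and -0.23 against normal, and the skeletal muscle list lies at -1.75 in week 2.

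The comparison of STZ FK1706 with normal vehicle asks what differs from normal in treated diabetic rats. No normal rats were given FK1706, so this comparison holds the effects of STZ and of the drug together. Txnip was 1.51-fold higher, at 11.45 ± 0.068 (SD, n = 3) against 10.85 ± 0.127, in all 3 weeks. Col1a1 (11.49 ± 0.43 against 12.08 ± 0.344, n = 3) and Col2a1 (8.06 ± 0.286 against 8.82 ± 0.347, n = 3) had lower values that did not pass. As lists, matrix, cartilage, fatty acid synthesis, myelinating Schwann cell and skeletal muscle genes were lower. With an estimated correlation they did not pass, with adjusted p = 0.201, 0.161, 0.201, 0.271 and 0.532 in that order.

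Txnip was the 1 gene that passed in limma (log2 difference 0.59, SE 0.072, adjusted p = 0.0367), with 570 at an unadjusted p under 0.05. At least 1.5-fold apart in each week were 2 genes, both lower and neither passing, against 2, 0 and 5 under the swapped labels. They were Ttc9b, a tetratricopeptide repeat gene (-1.19, adjusted p = 0.082), and Col10a1 (-0.90, adjusted p = 0.173). The deposited scale gave 106 genes, 1 higher and 105 lower, beside its median shift of all genes of -0.17. The limma count was 0 without any single array except the week 3 STZ vehicle array, where it was 2, and 0 without week 1 or week 3, with 401 to 857 genes at an unadjusted p under 0.05. It was 0 with no filter (777 unadjusted), with every probe set on its own (777) and with a prior without a trend (542).

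Of 29 lists 6 passed against normal rats, 1 higher and 5 lower, 0 of them with an estimated correlation. With fry 3 lists passed, 2 of them among the 6 (cartilage and bone, and ion channels). Glycolysis and polyol genes, with Txnip among them, were higher than no change (fry adjusted p = 0.0036). No change is again the level after normalization, which took out a median of -0.17. Matrix genes were lower (adjusted p = 2.91e-09, and adjusted p = 0.201 with an estimated correlation), with 0 of 39 members passing in limma over all genes, 12 lower at an unadjusted p under 0.05 and 9 adjusted over the list alone. Col1a1 had -0.59 (adjusted p = 0.082), Col1a2 -0.48, Timp1 -0.44 and Col3a1 -0.39. Cartilage and bone genes were lower (adjusted p = 1.69e-06, and adjusted p = 0.161 with an estimated correlation), with 0 of 6 over all genes, 4 at an unadjusted p under 0.05 and 4 adjusted over the list alone. Col2a1 had -0.76, Cnmd -0.50 and Acp5 -0.35.

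Fatty acid synthesis genes were lower (adjusted p = 7.59e-05, and adjusted p = 0.201 with an estimated correlation), with 0 of 16 over all genes, 7 at an unadjusted p under 0.05 and 5 adjusted over the list alone. The elongase gene Elovl6 had -0.41, the desaturase gene Scd -0.37, Dgat2 -0.50 and Me1 -0.35. Myelinating Schwann cell genes were lower (adjusted p = 0.000187, and adjusted p = 0.271 with an estimated correlation), with 0 of 17 over all genes, 5 at an unadjusted p under 0.05 and 2 adjusted over the list alone, Cnp (-0.37) and Mal (-0.27). Prx had -0.20, and the myelin protein gene Pmp22 had -0.10, or 0.02 with median scaling.

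Skeletal muscle genes were lower (adjusted p = 0.00505, and adjusted p = 0.532 with an estimated correlation), with 0 of 11 members passing over all genes or adjusted over the list alone and 4 lower at an unadjusted p under 0.05. Myl1 had -1.09, Tnnc2 -1.08, Tnni2 -0.75 and Myh1 -0.23. The skeletal muscle list did not pass without the week 2 normal array (0.378), without the week 3 FK1706 array (0.233) or on the deposited scale (0.203). Voltage-gated ion channel genes were higher as a list (adjusted p = 0.0387, and adjusted p = 0.271 with an estimated correlation), with 0 of 31 over all genes or adjusted over the list alone and 2 higher at an unadjusted p under 0.05. Hcn3 had 0.35, Cacna2d3 0.17, Scn11a 0.15 and Kcna1 0.15, and on the deposited scale Cacna2d3 had -0.0041, Scn11a -0.0174 and Kcna1 -0.0133. The ion channel list did not pass with no filter (0.109), a filter at the 60th percentile (0.191), or without the normal arrays of weeks 1 (0.176) or 3 (0.0613), the FK1706 arrays of weeks 1 (0.0848) or 3 (0.201), week 1 (0.169) or week 3 (0.118). Glycolysis and polyol genes did not pass against the other genes (adjusted p = 0.183), and Txnip rose over all genes and, adjusted over the list alone, Txnip rose and Akr1b1 fell (-0.25). Txnip had the largest moderated t of the list (8.16), and the list was not tested without it. Slc2a1, the glucose transporter GLUT1, had -0.22 and Eno1 0.15, or -0.01 on the deposited scale.

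Between weeks, 4 genes passed the limma F test. From week 1 to week 3, the splicing factor gene U2af2 rose by 0.80, with 0.21 in week 2 (adjusted p = 0.0352) and Rap1gap, which encodes a GTPase-activating protein of Rap1, rose by 0.50 (adjusted p = 0.0175), though it had -0.33 in week 2 against week 1. The BMP receptor gene Bmpr2 had -0.96, with -0.01 in week 2 (adjusted p = 0.0352), and Col3a1 had -0.37 in week 3 and -0.54 in week 2 (adjusted p = 0.0352). Week stands here for age, time since injection and sampling day together. At an unadjusted p under 0.05 there were 729 genes. On the deposited scale, where the signal falls from week to week, 4489 genes passed, 20 higher and 4469 lower. The count was 0 without the week 1 or week 3 STZ vehicle array or the week 3 normal array (538, 550 and 771 unadjusted). It was 1 without the week 1 FK1706 array, 2 without the week 1 normal or the week 3 FK1706 array and 8 without the week 2 STZ vehicle array. It was 1 with no filter and 0 with a prior without a trend (752 unadjusted).

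The difference between STZ vehicle and normal rats changed linearly over the weeks in 0 genes in limma, with 286 at an unadjusted p under 0.05. The difference between FK1706 and STZ vehicle did so in 0 genes, with 243. Both rest on 2 residual degrees of freedom. In simulated data the model recovered 96.5% and 97.5% of slopes of 1 log2 unit per week in these comparisons, 38.9% and 39.2% of slopes of 0.5, and 0% and 0.3% of slopes of 0.25. At a slope of 1, 7.74% and 7.76% of calls were false, and at 0.5 the shares were 8.04% and 11.3%. At 0.25 all 4 calls for STZ vehicle against normal were false, and 0 were false for FK1706 against STZ vehicle. Each slope was given to 1000 genes in 5 runs, so recovery may be lower where few genes change.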

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

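The deposited scale was added after the data had been seen; the other alternatives were set earlier. The matrix, cartilage and bone, fatty acid synthesis and myelinating Schwann cell lists were called lower in both STZ groups than in normal rats in all 12 fits that left out an array or week. Both comparisons use the same normal arrays, so their agreement is not independent. Some of the 12 fits dropped only an array of the group not compared, which keeps all compared arrays in place. With an estimated correlation 0 lists passed in any comparison (adjusted p from 0.0865 to 0.271 for these), so against other genes these calls rest on the preset correlation. Fry, which tests against no change, called the matrix (adjusted p = 0.0212) and cartilage and bone lists (0.000811) lower for STZ vehicle against normal and the cartilage and bone list (0.0036) lower for FK1706 against normal, but not the others. Of 2885 values of named genes under alternatives, 2697 kept direction and side of the threshold, 124 no longer passed, 23 newly passed and 41 changed sign. Most named genes did not pass in the main fit, so their staying on that side says little. The 124 values come from the few genes that did pass, whose calls were thus often lost. A fit that leaves 1 group without an array in a week assumes that the remaining pools vary alike. The offset compresses the folds of genes with signals near background, so differences of weak genes are hard to see. Except where stated, the cause of a change was not tested.

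On the deposited scale the counts were 16 genes for STZ vehicle against normal, 106 for FK1706 against normal and 4489 between weeks, and its construction keeps the signal shift between arrays. It gave 3 lists and 2 genes at least 1.5-fold apart in each week for FK1706 against STZ vehicle. With no filter 0 genes passed for STZ vehicle against normal, 0 for FK1706 against normal and 1 between weeks, and 26 (STZ vehicle against normal) and 19 (FK1706 against STZ vehicle) were at least 1.5-fold apart. With a prior without a trend 0 genes passed in each of STZ vehicle against normal, FK1706 against normal and weeks. With week left out as a block 1 gene passed for STZ vehicle against normal and 0 lists for FK1706 against STZ vehicle. Every probe set on its own gave 0 genes for FK1706 against normal and 2 at least 1.5-fold apart for FK1706 against STZ vehicle. At a filter at the 60th percentile 23 of 29 lists kept enough genes to be tested. It gave 4 lists for STZ vehicle against normal, where 2 of the 7 called otherwise (cartilage and bone, and mast cells and neutrophils) were not tested and glycolysis did not pass (adjusted p = 0.0556). It gave 3 for FK1706 against normal, where 2 of the 6 (cartilage and bone, and skeletal muscle) were not tested and ion channels did not pass (adjusted p = 0.191). It gave 3 and 0 genes at least 1.5-fold apart for STZ vehicle against normal and for FK1706 against STZ vehicle. In that order, the 30th percentile offset gave 3 and 0 genes, a minimum fold of 1.3 gave 22 and 7 and a minimum fold of 2 gave 0 and 0. The offset of 1 gave 2 for FK1706 against STZ vehicle. Fry gave 4 lists for STZ vehicle against normal, 0 for FK1706 against STZ vehicle and 3 for FK1706 against normal. All fry results given are for lists moving in 1 direction. Without regard to direction fry gave 7, 0 and 7 lists. Differences of the same week, which share an array by construction, gave a covariance of -0.0248 between the effects of STZ and FK1706. This lies within the range of -0.0257 to -0.0236 from unchanged simulated groups.

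Leaving out an array or week gave 0 to 9 genes for STZ vehicle against normal, 0 to 2 for FK1706 against normal, 0 to 8 between weeks and 0 to 5 lists for FK1706 against STZ vehicle. For FK1706 against STZ vehicle 0 genes passed in limma under every alternative. On the deposited scale Cacna2d3 (-0.0041), Eno1 (-0.0075), Kcna1 (-0.0133) and Scn11a (-0.0174) changed sign for FK1706 against normal, and Fkbp9 (-0.0538) for FK1706 against STZ vehicle. Median scaling turned Pmp22 (0.0246) for FK1706 against normal. Leaving out an array or week turned genes for STZ vehicle against normal, with ranges of -1.19 to 0.19 for Acta1, -1.08 to 0.29 for Myl1, -0.93 to 0.22 for Tnnt3 and -0.36 to 0.27 for S100a8. For FK1706 against STZ vehicle the ranges were -0.23 to 0.069 for Col9a2, -0.11 to 0.14 for Fkbp10, -0.37 to 0.064 for Fkbp5, -0.10 to 0.27 for Fkbp8, -0.016 to 0.045 for Fkbp9, -0.25 to 0.041 for Jun, -0.12 to 0.34 for Scn9a, -0.33 to 0.000134 for Vgf, -0.23 to 0.94 for Np4, -0.19 to 0.48 for S100a8, -1.39 to 0.0022 for Tnnc2 and -0.095 to 0.78 for Tpsb2.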

Other observations

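The tests of the week 2 normal array, of vertebral tissue, of muscle, of RNA degradation and of the clock were chosen after the results had been seen; the others were set earlier. Circadian clock genes differed widely between arrays without passing as a list for STZ vehicle against normal (adjusted p = 0.24). Dbp, a clock output gene, had differences of -1.14, 0.64 and -3.13 in weeks 1, 2 and 3, and Bmal1, its activator, 0.65, 0.07 and 0.77. Over all genes 0 of 9 clock genes passed in limma, with 3 at an unadjusted p under 0.05, and adjusted over the list alone Bmal1 rose (0.49) and Cry2 fell (-0.32). The clock list was called lower without week 2 (adjusted p = 9.44e-05), its normal array (0.00117) or its STZ vehicle array (0.0056).

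In the same comparison the heat shock and chaperone list (adjusted p = 0.483), the antioxidant list (0.897) and the unfolded protein response list (0.784) did not pass. In limma 0 of their members passed over all genes, with 3, 4 and 1 at an unadjusted p under 0.05. Adjusted over the list alone, 2 of 24 chaperones fell, Cryab (-0.41), a small heat shock protein gene, and Hspe1 (-0.24), a mitochondrial chaperonin gene. Among 26 antioxidant genes the glutathione transferase gene Gstm2 rose (0.51) and thioredoxin Txn1 fell (-0.25), and among 25 genes of the unfolded protein response Sdf2l1 fell (-0.46). Insulin transcripts lay below the filter, with Ins1 at a mean of 7.33 and Ins2 at 6.41 against a limit of 7.37.

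For STZ vehicle against normal, other lists did not pass. Ion channels had an adjusted p of 0.0717 (0.037 and higher without the week 3 STZ vehicle array; against no change, fry gave 0.00984 and higher), respiratory chain genes 0.0717 (0.00409 and lower on the deposited scale), synaptic release 0.329, macrophages 0.576, adipocytes 0.576, cell division 0.576 and immunophilins 0.576. Large-diameter neurons had 0.666, immediate early genes 0.784, glucocorticoid response 0.829, vessels 0.865, fatty acid oxidation 0.936, cholesterol synthesis 0.95 and satellite glia 0.998. Of 1458 probe sets without a gene symbol, 0 passed in limma for STZ vehicle against normal, with 133 at an unadjusted p under 0.05.

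Other lists crossed the threshold only under some alternatives. For FK1706 against STZ vehicle, cholesterol synthesis (adjusted p = 0.213) was called lower without the week 3 STZ vehicle array (0.0405) and clock genes (0.876) higher without the week 2 STZ vehicle array (0.0496). For FK1706 against normal, clock genes (0.433) were called lower without week 2 (0.00545) or its normal array (0.00828), and mast cell and neutrophil genes (0.615) lower without week 3 (0.0392) or its FK1706 array (0.0171). Respiratory chain genes (0.0632) were called lower on the deposited scale (5.46e-05), with week left out as a block (0.0469) and without the week 1 FK1706 array (0.0395). Synaptic release genes (0.0526) were called higher with median scaling (0.0315), with week left out (0.0403) and without the week 3 STZ vehicle array (0.0402), and interferon-stimulated genes (0.11) lower with no filter (0.0104). Against no change, which fry tests, glycolysis and polyol genes, with Txnip among them, were called higher (0.0036), and against other genes they did not pass (0.183).

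The matrix list was called lower in STZ vehicle than in normal rats (adjusted p = 3.18e-16, and adjusted p = 0.116 with an estimated correlation), with 4 of 39 members passing over all genes. Of 10000 random lists matched on mean signal none had a median as low, with a share of 1e-04, the smallest they can give. The matrix genes were thus lower than other genes of like signal. Quantile normalization had already given all arrays the same distribution of signals. The matched lists are therefore a weak test of scaling that depends on intensity, and cannot exclude it by themselves. The week 2 normal array alone is not the source, since the higher of the medians of weeks 1 and 3 was -0.219. A uniformly smaller share of connective tissue would lower fibroblast transcripts and collagens alike, but 26 fibroblast genes had a median 0.359 above that of 16 collagens (permutation p = 2e-04). Those 26 genes include matrix proteins other than collagens, and the permutation over genes treats them as independent, which they are not. Less vertebral cartilage or bone in the STZ pools may contribute and stays open beside an effect of diabetes. Acp5, Cnmd and Ctsk had a median of -0.531, below the collagen median of -0.409, as such carry-over would give. They did not follow the collagens from array to array once group and week were removed (r = -0.202). With 4 residual degrees of freedom that r cannot decide, and only 3 such genes could be tested.

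Muscle transcripts were high in the week 2 normal array, where 11 muscle genes had a median excess of 1.26 over the other normal arrays and 9 were higher. Carry-over of muscle stays open, since that excess is what prompted the question and cannot also answer it. Acta1 was at 10.77 there and between 8.41 and 10.13 in the other 8 arrays, lowest in the week 3 FK1706 and week 2 STZ vehicle arrays. The 3' to 5' signal ratio of beta-actin was 1.09 there against 1.02 to 1.24 in the other arrays, which gave no sign of degraded RNA in that pool. A ratio of beta-actin only cannot exclude degradation. The design gives no biological explanation to test here.

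Clock output genes may differ between arrays because ganglia were taken at different clock phases. Over the 9 arrays Bmal1 ran against the mean of Dbp, Nr1d1, Nr1d2 and Hlf (Pearson r = -0.769, exact permutation p = 0.0149, adjusted 0.0298; Spearman rho = -0.45, exact permutation p = 0.23). Without the 2 arrays farthest from the median r was -0.23, so the relation rests on those arrays, while r was -0.544 within groups and -0.884 within weeks. A constant effect of STZ would give Dbp 1 sign in all weeks. In STZ vehicle rats, however, Dbp differed by 0.637 in week 2, within the spread of 0.748 that 95% of 501 genes of like signal kept to. In FK1706 rats Dbp differed from the same normal arrays by -1.47, -0.105 and -1.97 in weeks 1, 2 and 3. Bmal1 differed there by 0.645, 0.441 and 0.915, so each gene kept 1 sign. Clock phase and an effect of STZ cannot be told apart, since sampling hours are not given in the sources used here.

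It was tested whether FK1706 might move genes lowered by STZ back towards normal. The 100 genes lowest under STZ in a pair of weeks had a median FK1706 difference in the remaining week of 0.06, -0.06 and -0.01. Among matched lists these stood at percentiles 97.9, 1.83 and 49.9, so the test does not decide.

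Other splits of the samples were counted for each result. With 10 splits, or 4 swaps of labels within weeks, the splits are too few for a share under 0.05. For STZ vehicle against normal 1 split, the real one, gave as many genes (7, highest other 0) and 1 as many lists (7, highest other 5). For FK1706 against STZ vehicle 10 splits gave as many genes (0, highest other 0) and 7 as many lists (1, highest other 4). For FK1706 against normal 2 gave as many genes (1, highest other 1) and 1 as many lists (6, highest other 5). The other split with 1 gene exchanges labels within 1 week only. For STZ vehicle against normal every other split called lists, from 1 to 5 of them. The other splits called 0 to 4 for FK1706 against STZ vehicle and 0 to 5 for FK1706 against normal. List calls at the preset correlation thus also arise without the real grouping. For changes over the weeks all 4 swaps gave 0 genes for STZ and all 4 gave 0 for FK1706 (limma, 286 and 243 at an unadjusted p under 0.05 in the real labels). Between weeks 2 of 36 splits gave as many genes (4, highest other 6), so chance is not excluded there.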
